A study of Arabidopsis thaliana with 4 samples.

How the data were processed

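RNA was measured by Illumina sequencing in 4 libraries of wild-type Arabidopsis thaliana (accession Col-0), 2 from the wounded region of leaf explants at the moment of detachment (time 0) and 2 from explants kept for 2 days on culture medium in darkness. Groups and replicate numbers came from the sample titles, and the columns of the table were matched to samples by name, the time 0 columns by the description and title that GEO records and the 2-day columns, whose names give the culture but not the day, by the title. Every library had a group, so none was left out.

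The authors deposited one table of TPM (transcripts per 1000000, a read count per gene divided by transcript length and scaled to a total of 1000000 per library), rounded to 2 decimals. Trim Galore 0.5.0, STAR 2.7.2b, RSEM 1.3.2 and the TAIR10 genome are named, per the submitters' processing notes. The annotation release, the strand setting and the filters are not given in the sources used here. The values in each of the 4 columns sum to 1000000 within rounding, and TPM keeps no depth. The depth of each library is therefore unknown, and no counting interval, detection floor or count-based test was applied. RSEM divides reads that match several genes between them, which makes the values of near-identical copies depend on that division, and overlapping genes on opposite strands cannot be told apart if the strand was not used.

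The table lists 37686 genes by locus identifier, of which 12299 are at 0 in all 4 libraries. Symbols came from the TAIR10.1 annotation, in which 37390 of the identifiers occur as locus tags. Because the named build is TAIR10 and not TAIR10.1, no coordinates are given, and the reference served only for names, product descriptions, overlaps between genes and shared sequence. For each named gene the share of 50-base windows of its transcripts that also occur in transcripts of other genes, on the sense or the antisense strand, was computed with Python 3.11.15. Figures were drawn with matplotlib 3.10.9.

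Genes with a mean of at least 1 TPM over the 4 libraries were tested (19078 genes, with 18608 below the limit). A gene near 0 TPM in 1 group passes this limit only if it is higher in the other. The comparison of 2 days with time 0 was fitted to log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called higher or lower at an adjusted p below 0.05. Log2 differences are on the log2(TPM + 1) scale, which understates the change of genes with low values. The fit has 2 residual degrees of freedom per gene, and limma draws on all genes for its estimate of the spread. Nothing in the labels says that the 2 libraries of a group came from separate cultures or plants, so p-values measure only the spread between these libraries, which may be technical.

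Gene lists were fixed from general knowledge of leaf explants, wounding and root regeneration before the data were examined. A list member whose identifier and symbol do not pair in the reference was left out (14 members, with 446 kept). Each of the 27 lists with tested members was compared with the other genes by camera in limma with a preset inter-gene correlation of 0.01, adjusted over lists, and again with the correlation estimated from the data. A list of shoot meristem markers had 0 tested members. Members past the threshold were counted after adjustment over all genes tested and adjusted over the list alone. The rule for named genes was also fixed in advance. It took the 5 nuclear genes with a symbol that rose most and the 5 that fell most among called genes whose groups do not overlap, 2 members of each list with the largest change in the direction most called members took and 1 in the other direction, and 12 candidate genes of root regeneration. Where as many called members rose as fell, as in the jasmonate list, the 2 were taken from those that rose. Genes named outside this rule are marked as chosen after their values were seen. Sets of sugar-responsive and clock-controlled genes are the exception, fixed before those sets were tested.

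The procedure was tested on data simulated from the mean of each gene over the 4 libraries, with 19046 genes passing the filter. Genes were drawn independently of each other and most were left unchanged, whereas 68.78% of tested genes were called in the real data. The reads per TPM and the spread between libraries were assumed values, alike for all genes and not estimated from these libraries. The recovery and false calls below therefore hold for those settings and do not measure the error in this dataset. For the comparison of 2 days with time 0 it recovered 96 of 99 genes changed by 2-fold and 98 of 98 changed by 4-fold, with 15 calls among unchanged genes. Of 200 simulated lists of 20 unchanged genes, 5 had an unadjusted camera p below 0.05 and 0 were called after adjustment. Since these genes varied independently, the lists cannot show whether the preset correlation limits false calls in lists of co-regulated genes.

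Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, scaling by trimmed means of M-values (TMM) computed on the TPM, quantile normalization, rescaling without organelle genes and the 100 most abundant genes, limma without the trend or with robust variances, the replicate number as a block, an adjusted p below 0.01, a minimum change of 2-fold, and leaving out each library in turn. When a library is left out, the lone library of its group is assumed to vary like the other group. Averaging the time 0 libraries into 1 sample and keeping the list members without a paired symbol were added after seeing the data.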

Results

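Transcript levels were measured in leaf explants of Arabidopsis thaliana, a small plant of the mustard family, to follow the early response of a detached leaf that can form new roots at its wound. Seedlings of the wild-type accession Col-0 were grown for 12 days at 22 °C under 16 h of light and 8 h of darkness. Leaves were then cut off with part of the petiole and placed on B5, a plant culture medium, with sucrose and in the dark. The wounded region was sampled at time 0 and after 2 days of culture, with 2 libraries per group. The 2-day explants differ from time 0 in time since detachment, darkness, medium and age at once, and these were not varied separately. The time of day of sampling is not given in the labels and may differ as well. Values are given as mean TPM ± SD (n = 2 libraries per group) as deposited, and the sequencing depth behind them is unknown.

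After 2 days of culture 14 of 21 tested regulators of root founder cells and primordia were higher than at time 0, and 38 of 41 nuclear photosynthesis genes were lower. LBD16 (AT2G42430), a transcription factor of root initiation, rose from 0.045 ± 0.0212 to 21 ± 1.73 TPM. Transcripts of 41 nuclear photosynthesis genes made up 14.75% and 14.2% of all TPM in the time 0 libraries and 2.82% and 2.476% in the 2-day libraries. The named gene that rose most was EARLI1 (AT4G12480), a lipid-transfer-like protein, from 0.44 ± 0.0849 to 3907 ± 333.5 TPM (log2 difference 11.40, limma adjusted p = 1.53e-06). Its neighbour AZI1 (AT4G12470), which acts in systemic immunity, went from 0.825 ± 0.00707 to 2018 ± 288 TPM.

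Among nuclear genes with a symbol in the reference, the other 3 with the largest rises encode 2 extensins, structural proteins of the cell wall, and a peroxidase. Extensin EXT3 (AT1G21310) increased from 1.22 ± 0.226 to 2733 ± 459 TPM. Extensin EXT4 (AT1G76930) increased from 3.08 ± 0.523 to 3481 ± 936 TPM. Of the 50-base windows of EXT3 transcripts, 23.9% overlap a gene on the opposite strand, which leaves its level uncertain. Peroxidase PRX52 (AT5G05340) increased from 0.165 ± 0.0778 to 613 ± 6.78 TPM. The 5 largest falls among such genes included the germin-like protein GER3 (AT5G20630), from 1066 ± 21.4 to 1.71 ± 1.68 TPM. The asparagine synthetase ASN1 (AT3G47340) fell from 549.7 ± 8.26 to 1.28 ± 1.53 TPM. SEN1 (AT4G35770), a gene induced by darkness and senescence, fell from 1208 ± 19.2 to 5.91 ± 6.14 TPM. The carbonic anhydrases CA2 (AT5G14740) and CA1 (AT3G01500) fell with log2 differences of -7.24 and -6.96. CA2 stood at 909 ± 20.4 TPM at time 0 and 5.33 ± 2.78 TPM at 2 days. CA1 stood at 1002 ± 23.7 TPM at time 0 and 7.55 ± 4.04 TPM at 2 days, and it shares 8.9% of its windows with another gene. All 10 changes passed limma's test, with adjusted p between 1.53e-06 and 0.000338.

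Of 19078 genes tested, 7485 were higher and 5636 lower at 2 days (limma, adjusted p below 0.05). At least 2-fold changes were found in 2958 of the higher and 1982 of the lower genes. The 2 groups did not overlap in 16404 genes (85.98%), where chance gives 33.33% for 2 against 2 libraries. The share of called genes that were higher was 57.05%, and it was 47.05% after quantile normalization (6385 higher, 7187 lower), which moved the median of all tested genes from 0.09 to -0.06 on the log2 scale. Rescaling without organelle genes and the 100 most abundant genes moved that median to -0.02 and gave 6495 higher and 6694 lower genes, so the direction of small changes depends on the scaling. Of the 27 gene lists, 10 passed camera's test, and each of the 10 had an adjusted p of 0.601 with an estimated correlation, so that 0 were called in that form of the test.

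Regulators of root founder cells and primordia mostly rose: 14 of 21 tested members were higher, 3 were lower and 4 did not pass (the same counts adjusted over the list alone). The list median was 1.49 on the log2 scale (camera adjusted p = 0.0314 and adjusted p = 0.601 with an estimated correlation). Of 29 fixed members 21 were tested, and members near 0 at time 0 were tested only if they rose, so the counts lean upwards. Over the 11 members with a mean of at least 5 TPM the median was 0.16. The camera call was lost with a pseudocount of 5 (adjusted p = 0.0612) and among genes with a mean of at least 5 TPM (adjusted p = 0.678), and over the alternatives with a preset correlation the adjusted p ran from 0.0133 to 0.678. LBD29 (AT3G58190), an auxin-induced relative of LBD16, was listed at 0 in both time 0 libraries and at 12.43 and 18.99 TPM at 2 days (limma adjusted p = 6.33e-05). WOX11 (AT3G03660), a homeobox gene of root founder cells, rose from 0.085 ± 0.0778 to 2.42 ± 0.311 TPM (limma adjusted p = 0.000591). WOX5 (AT3G11260), a gene of the root stem cell niche, rose from 0.035 ± 0.0495 to 2.4 ± 1.22 TPM (limma adjusted p = 0.00403). TMO5 (AT3G25710), a regulator of vascular cell division, fell from 53.2 ± 1.9 to 5.73 ± 0.608 TPM. Among candidates below the expression limit and hence untested, WOX12 (AT5G17810) was listed at 0 in both time 0 libraries and at 0.19 and 0.23 TPM at 2 days, and WOX7 (AT5G05770) at 0 in both time 0 libraries and at 0.43 and 0.5 TPM at 2 days. PLT1 (AT3G20840) and PLT2 (AT1G51190) were listed at 0 in all 4 libraries.

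Auxin biosynthesis genes changed in both directions, with 9 of 13 tested members higher, 3 lower and 1 not past the threshold (the same counts adjusted over the list alone), and the list did not pass as a group (median log2 difference 1.00, camera adjusted p = 0.135). The nitrilase NIT2 (AT3G44300) rose from 0.15 ± 0.0849 to 158 ± 23.9 TPM and shares 5.8% of its windows with another gene. CYP79B2 (AT4G39950), which converts tryptophan to indole-3-acetaldoxime, rose from 4.53 ± 0.721 to 381 ± 13.9 TPM. The flavin monooxygenase YUC3 (AT1G04610) fell from 20.6 ± 1.53 to 0.085 ± 0.00707 TPM. ASA1 (AT5G05730), a subunit of the enzyme that starts tryptophan synthesis, rose from 53.6 ± 2.11 to 88.7 ± 20.13 TPM (limma adjusted p = 0.0112), with 6.2% of its windows overlapping a gene on the opposite strand. Its call was lost without time 0 replicate 1 (adjusted p = 0.0702), without time 0 replicate 2 (adjusted p = 0.0529) and with the time 0 libraries averaged, an alternative chosen after seeing the data (adjusted p = 0.0614), within a range of 0.00412 to 0.0702 over all its alternatives. YUC1 (AT4G32540) stood at 0.07 and 0.03 TPM at time 0 and was listed at 0 in both 2-day libraries, and YUC4 (AT5G11320) stood at 0.07 and 0.12 TPM at time 0 and at 0 and 0.12 TPM at 2 days, and neither was tested.

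**Figure D1:**
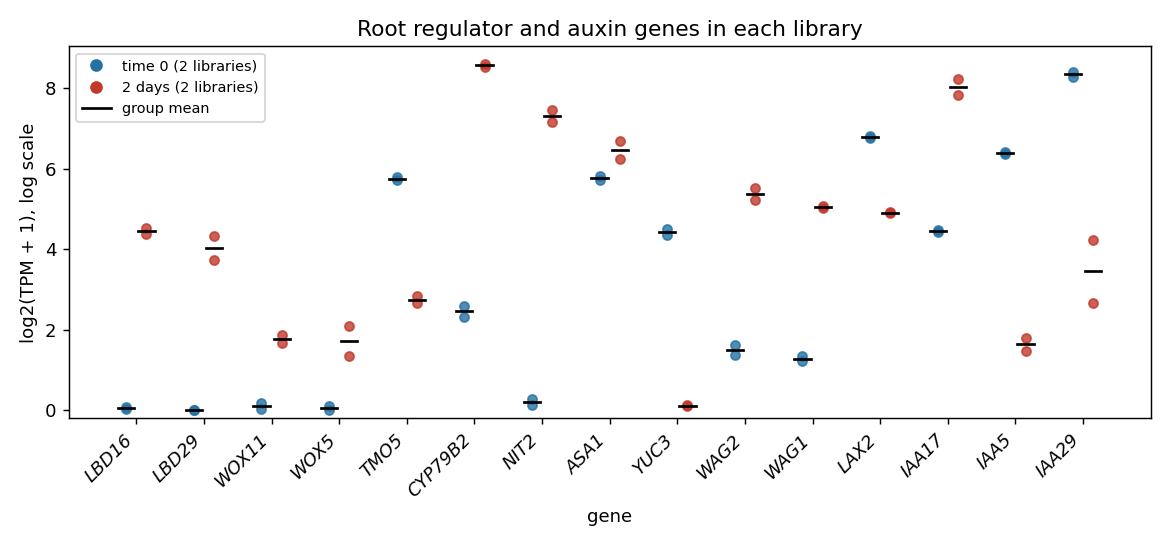
Expression of the named root regulator and auxin genes in each library, as log2(TPM + 1) on the vertical axis, with one point per library (2 per group, blue for time 0 and red for 2 days) and a black bar at the group mean. LBD16, LBD29, WOX11 and WOX5 lie near 0 in both time 0 libraries and above 1 in both 2-day libraries, while YUC3, IAA5 and IAA29 lie lower at 2 days.

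Genes of the Aux/IAA and GH3 families, which respond to auxin, mostly fell: 21 of 31 tested members were lower, 3 higher and 7 did not pass (the same counts adjusted over the list alone). Camera compared the list, whose median log2 difference was -0.84, with all other genes (camera adjusted p = 3.65e-05 and adjusted p = 0.601 with an estimated correlation). IAA29 (AT4G32280) went from 325 ± 21.1 to 11.6 ± 8.94 TPM. IAA5 (AT1G15580) went from 83 ± 1.94 to 2.13 ± 0.481 TPM. IAA17 (AT1G04250) rose from 20.9 ± 0.714 to 264 ± 51.5 TPM. Of 16 tested auxin transport genes, 7 were higher, 7 lower and 2 not past the threshold (7 higher and 8 lower adjusted over the list alone). Their median log2 difference was -0.19 and their mean 0.46, and camera, whose direction was down, gave an adjusted p of 0.738. The kinases WAG2 (AT3G14370) and WAG1 (AT1G53700), which act on auxin efflux carriers, both rose. The level of WAG2 went from 1.84 ± 0.354 to 40.8 ± 6.05 TPM. That of WAG1 went from 1.44 ± 0.17 to 32.3 ± 0.919 TPM. The auxin influx carrier LAX2 (AT2G21050) fell from 109.9 ± 1.7 to 29.2 ± 0.198 TPM.

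Of 5 tested wound-induced transcription factors linked to regeneration and with a paired symbol, 4 were higher, 0 lower and 1 did not pass (the same counts adjusted over the list alone). Over these genes the median log2 difference was 1.99 (camera adjusted p = 0.0474 and adjusted p = 0.601 with an estimated correlation). Without a filter the median was 0.47 over 9 members. The counts leave out members without a paired symbol, named here after their values were seen. Of those, WIND2 (AT1G22190) fell (log2 difference -0.75, limma adjusted p = 0.00215), and WIND3 (AT1G36060) and ERF114 (AT5G61890) rose (3.98 and 3.96). RAP2.6L (AT5G13330) rose from 0.14 ± 0 to 21.1 ± 1.13 TPM. ERF115 (AT5G07310), which acts in the replacement of damaged cells, rose from 0.22 ± 0.0283 to 6.74 ± 0.00707 TPM. The group's call was lost without time 0 replicate 1 (adjusted p = 0.0595), without 2-day replicate 1 (adjusted p = 0.0531), without 2-day replicate 2 (adjusted p = 0.0693), without a filter (adjusted p = 0.0693), with a pseudocount of 5 (adjusted p = 0.0612) and from a mean of 5 TPM (adjusted p = 0.277), with a range of 0.0363 to 0.277 over the alternatives with a preset correlation. RRTF1 (AT4G34410), also known as ERF109, stood at 0.45 and 0.35 TPM at time 0 and at 0 and 0.04 TPM at 2 days and was not tested, and 59.2% of its windows overlap a gene on the opposite strand.

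Jasmonate synthesis and response genes went both ways, with 12 of 28 tested members higher, 12 lower and 4 not past the threshold (the same counts adjusted over the list alone; camera adjusted p = 0.738). The list's median and mean log2 differences were both 0.02 while camera's direction was down. CORI3 (AT4G23600) rose from 0.47 ± 0.0141 to 27.5 ± 14.5 TPM. The lipoxygenase LOX2 (AT3G45140) rose from 7.71 ± 0.099 to 114 ± 57.7 TPM. The storage protein VSP2 (AT5G24770), like CORI3 and LOX2 a jasmonate-responsive gene, fell from 143 ± 2.47 to 5.8 ± 2.09 TPM. In the ethylene list 5 of 13 tested members were higher, 4 lower and 4 not past the threshold (the same counts adjusted over the list alone; camera adjusted p = 0.738), with a median log2 difference of -0.04, a mean of 0.47 and a camera direction of up. The ACC synthases ACS7 (AT4G26200) and ACS2 (AT1G01480) both rose. The level of ACS7 went from 0.01 ± 0.0141 to 7.54 ± 0.148 TPM. That of ACS2 went from 0.01 ± 0.0141 to 3.93 ± 1.4 TPM. ACS8 (AT4G37770) fell from 36.9 ± 0.29 to 12.3 ± 5.76 TPM.

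Salicylate, camalexin and defence genes were higher in 7 of 14 tested members and lower in 1, with 6 not past the threshold (the same counts adjusted over the list alone; camera adjusted p = 0.217). Without 2-day replicate 2 this list passed (adjusted p = 0.0464), within a range of 0.0464 to 0.325 over the alternatives with a preset correlation. With all libraries the list had an adjusted p = 0.684 with an estimated correlation. The cytochrome P450 CYP71A12 (AT2G30750), of indole defence metabolism, rose from 0.035 ± 0.0212 to 80.4 ± 50.3 TPM and shares 2.7% of its windows with other genes. The receptor-like kinase FRK1 (AT2G19190) rose from 0.005 ± 0.00707 to 19.5 ± 4.3 TPM. EDS1 (AT3G48090), a regulator of immunity, fell from 24.9 ± 2.26 to 14.9 ± 0.0636 TPM. Of 6 tested low-oxygen genes, 4 were higher, 0 lower and 2 not past the threshold (the same counts adjusted over the list alone; camera adjusted p = 0.141), including the haemoglobin HB1 (AT2G16060), from 12.2 ± 0.7 to 50.3 ± 0.226 TPM, and the sucrose synthase SUS1 (AT5G20830), from 5.34 ± 0.106 to 18 ± 2.94 TPM.

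Glucosinolate synthesis genes, which make sulphur-containing defence compounds, rose in 9 of 9 tested members (9 adjusted over the list alone). The list median was 1.98 on the log2 scale (camera adjusted p = 0.000419 and adjusted p = 0.601 with an estimated correlation). CYP83B1 (AT4G31500) increased from 83.4 ± 0.658 to 1002 ± 57.1 TPM. CYP79F2 (AT1G16400) increased from 0.595 ± 0.0212 to 39.9 ± 1.09 TPM and shares 2.7% of its windows with another gene. In phenylpropanoid and flavonoid synthesis 7 of 8 tested members were higher, 0 lower and 1 not past the threshold (the same counts adjusted over the list alone). Camera compared the list, whose median log2 difference was 1.74, with all other genes (camera adjusted p = 0.00823 and adjusted p = 0.601 with an estimated correlation). PAL1 (AT2G37040), the entry enzyme of the pathway, rose from 23.3 ± 0.354 to 200.4 ± 10.7 TPM. The flavonoid gene F3H (AT3G51240) stood at 1.47 ± 0.318 TPM at time 0 and 20.8 ± 1.25 TPM at 2 days (limma adjusted p = 2.84e-05), but 84.5% of its windows overlap a gene on the opposite strand, so this rise is uncertain.

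Nuclear photosynthesis genes fell in 38 of 41 tested members, with 2 higher and 1 not past the threshold (the same counts adjusted over the list alone). Over these genes the median log2 difference was -2.31 (camera adjusted p = 4.19e-14 and adjusted p = 0.601 with an estimated correlation). The light-harvesting gene LHCB1.4 (AT2G34430) fell from 5595 ± 218 to 102 ± 43 TPM. LHCB1.2 (AT1G29910) fell from 4445 ± 90.2 to 256 ± 16.9 TPM. These copies share 13.7% and 10.6% of their windows with other genes, and 13.6% of the LHCB1.4 windows overlap a gene on the opposite strand, which leaves the level of each uncertain. The summed TPM of the 5 LHCB1 genes fell too, with log2 differences of -2.55 to -2.19 over the pairs of libraries. The sum does not depend on how reads were divided among these 5 copies. It does not remove opposite-strand overlap, which covers 100% of the windows of LHCB1.5, singled out after its values were seen. LHCB2.1 (AT2G05100) moved the other way, from 176 ± 2.65 to 332 ± 10 TPM (limma adjusted p = 7.93e-05), and shares 21.9% of its windows with another LHCB2 gene. Markers of the guard cell lineage fell as well, in 5 of 6 tested members with 1 not past the threshold (the same counts adjusted over the list alone). The list median was -0.87 on the log2 scale (camera adjusted p = 0.0297 and adjusted p = 0.601 with an estimated correlation). TMM (AT1G80080) went from 7.33 ± 0.148 to 0.94 ± 0.212 TPM. FAMA (AT3G24140) went from 25.9 ± 0.0424 to 9.79 ± 0.262 TPM. The guard cell call was lost from a mean of 5 TPM (adjusted p = 0.257) and without 2-day replicate 2 (adjusted p = 0.0575), within 0.00225 to 0.257 over the alternatives with a preset correlation.

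Genes known to be induced by darkness or sugar starvation fell during culture in the dark on sucrose, with 13 of 15 tested members lower, 1 higher and 1 not past the threshold (the same counts adjusted over the list alone). Camera compared the list, whose median log2 difference was -2.13, with all other genes (camera adjusted p = 1.37e-05 and adjusted p = 0.601 with an estimated correlation). ASN1 and SEN1 fell most in this list. PIF5 (AT3G59060), a factor of dark growth, stood at 56.5 ± 1.28 TPM at time 0 and 68.2 ± 7.94 TPM at 2 days (limma adjusted p = 0.0473). Its call was lost in 9 of 15 alternatives, among them all 3 other scalings, both fits without a time 0 library (adjusted p = 0.202 without replicate 1 and 0.145 without replicate 2) and the fit without 2-day replicate 2 (adjusted p = 0.0665), over a range of 0.0106 to 0.21. Senescence and chlorophyll breakdown genes were higher in 7 of 10 tested members and lower in 1, with 2 not past the threshold (the same counts adjusted over the list alone; camera adjusted p = 0.198). The senescence regulators NAC092 (AT5G39610) and NAP (AT1G69490) both rose. The level of NAC092 went from 1.66 ± 0.24 to 11.7 ± 3.72 TPM. That of NAP went from 1.72 ± 0.368 to 11.7 ± 5.88 TPM. The chlorophyll b reductase NYC1 (AT4G13250) fell from 79.6 ± 3.06 to 42.5 ± 0.884 TPM.

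All 12 tested circadian clock genes changed, 5 upwards and 7 downwards (the same counts adjusted over the list alone). Over these genes the median log2 difference was -0.96 (camera adjusted p = 0.334). With a mean of at least 5 TPM, which removes clock genes that were low at time 0, the list passed in the downward direction (adjusted p = 0.00599, within 0.00599 to 0.59 over the alternatives with a preset correlation). With the limit of 1 TPM the list had an adjusted p = 0.625 with an estimated correlation. The evening gene TOC1 (AT5G61380) fell from 111 ± 1.07 to 25 ± 0.0636 TPM. The morning gene LHY (AT1G01060) rose from 0.1 ± 0.0141 to 5.41 ± 0.0636 TPM. BOA (AT5G59570) stood at 56.8 ± 1.32 TPM at time 0 and 6.36 ± 1.94 TPM at 2 days, a fall that is uncertain because 42.6% of its windows overlap a gene on the opposite strand.

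DNA replication and S-phase genes rose in 15 of 19 tested members and fell in 1, with 3 not past the threshold (16 higher and 1 lower adjusted over the list alone). The list median was 0.73 on the log2 scale (camera adjusted p = 0.00659 and adjusted p = 0.601 with an estimated correlation). The ribonucleotide reductase gene TSO2 (AT3G27060) rose from 54.5 ± 2.93 to 127 ± 9.8 TPM. The sliding clamp PCNA1 (AT1G07370) rose from 15.2 ± 0.629 to 34.8 ± 1.13 TPM. CYCD3;2 (AT5G67260) fell from 13.3 ± 2.46 to 7.83 ± 0.481 TPM, a call lost without 2-day replicate 1 (adjusted p = 0.0628) and without 2-day replicate 2 (adjusted p = 0.0863), within 0.00303 to 0.0863 over its alternatives. Among 25 tested G2 and mitosis genes, 8 were higher, 3 lower and 14 did not pass (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.198). The cyclins CYCB1;3 (AT3G11520) and CYCB2;2 (AT4G35620) both rose. The level of CYCB1;3 went from 2.8 ± 0.24 to 8.65 ± 1.22 TPM. That of CYCB2;2 went from 3.5 ± 0.00707 to 9.14 ± 0.17 TPM. CYCA2;3 (AT1G15570) fell from 13.7 ± 0.523 to 3.56 ± 0.0919 TPM.

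Ribosome biogenesis genes rose in 9 of 13 tested members, with 0 lower and 4 not past the threshold (the same counts adjusted over the list alone). Camera compared the list, whose median log2 difference was 0.40, with all other genes (camera adjusted p = 0.0314 and adjusted p = 0.601 with an estimated correlation). The nucleolar proteins FIB2 (AT4G25630) and NOP56 (AT1G56110) both rose. The level of FIB2 went from 20.7 ± 0.608 to 53.4 ± 0.742 TPM. That of NOP56 went from 65.1 ± 1.63 to 123 ± 1.1 TPM. The list lost its call after rescaling without the most abundant genes (adjusted p = 0.063) and without time 0 replicate 2 (adjusted p = 0.0621), within 0.0069 to 0.063 over the alternatives with a preset correlation. Cell wall loosening genes were higher in 11 of 17 tested members and lower in 5, with 1 not past the threshold (the same counts adjusted over the list alone; camera adjusted p = 0.303). The wall-remodelling enzyme XTH20 (AT5G48070) rose from 0.025 ± 0.0354 to 29 ± 4.26 TPM, the expansin EXPA17 (AT4G01630) was listed at 0 in both time 0 libraries and at 11.98 and 31.3 TPM at 2 days (limma adjusted p = 0.000531), and XTH25 (AT5G57550) fell from 5.4 ± 0.099 to 0.175 ± 0.0495 TPM.

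Of 15 tested cytokinin genes, 3 were higher, 9 lower and 3 not past the threshold (the same counts adjusted over the list alone). Over these genes the median log2 difference was -0.91 (camera adjusted p = 0.072). The response regulator ARR4 (AT1G10470) fell from 53.1 ± 1.46 to 3.02 ± 0.622 TPM. The cytokinin oxidase genes CKX6 (AT3G63440) and CKX1 (AT2G41510) both changed, but their values are uncertain because 81.9% and 22.1% of their windows overlap a gene on the opposite strand. The level of CKX6 went from 61.3 ± 0.778 to 3.62 ± 0.12 TPM (limma adjusted p = 6.91e-06). That of CKX1 went from 0.465 ± 0.0919 to 7.68 ± 2.29 TPM (limma adjusted p = 0.00029).

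Other tissue markers moved in different directions, and none of these lists passed camera's test. Of 7 tested xylem markers 0 were higher and 3 lower (0 and 2 adjusted over the list alone; camera adjusted p = 0.178), including the proteases XCP2 (AT1G20850), from 152 ± 2.17 to 70.5 ± 1.54 TPM, and XCP1 (AT4G35350), from 78.8 ± 1.53 to 43.4 ± 1.83 TPM. Of 4 phloem markers 1 was higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 0.803): PP2-A1 (AT4G19840) went from 85.7 ± 0.0424 to 224 ± 2.22 TPM, with 16.0% of its windows overlapping a gene on the opposite strand, and SEOR1 (AT3G01680) from 79.2 ± 1.83 to 35.5 ± 4.07 TPM. In the procambium and cambium list 2 of 4 were higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 0.658). The cambium regulators WOX4 (AT1G46480) and PXY (AT5G61480) both rose. The level of WOX4 went from 3.14 ± 0.17 to 19.7 ± 1.45 TPM. That of PXY went from 13.6 ± 0.29 to 29.4 ± 0.841 TPM. TMO6 (AT5G60200) fell from 11.2 ± 0.0424 to 7.79 ± 0.672 TPM, a call lost without time 0 replicate 1 (adjusted p = 0.0594), without time 0 replicate 2 (adjusted p = 0.0561) and with the time 0 libraries averaged (adjusted p = 0.0575), within 0.00164 to 0.0594 over its alternatives.

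Epidermis markers were higher in 3 of 7 tested members and lower in 2 (the same adjusted over the list alone; camera adjusted p = 0.803). The wax synthesis genes CER1 (AT1G02205) and CER6 (AT1G68530) both rose. The level of CER1 went from 7.24 ± 0.106 to 134 ± 23 TPM. That of CER6 went from 305 ± 0.141 to 618 ± 8.99 TPM. PDF1 (AT2G42840) fell from 198 ± 5.51 to 1.96 ± 0.955 TPM. Of 6 leaf polarity genes 1 was higher and 4 lower (the same adjusted over the list alone; camera adjusted p = 0.213). YAB1 (AT2G45190) and YAB3 (AT4G00180), which specify the lower leaf side, both fell. The level of YAB1 went from 21.6 ± 1.13 to 6.21 ± 2.09 TPM. That of YAB3 went from 54.1 ± 2.38 to 26.6 ± 0.262 TPM. REV (AT5G60690), which specifies the upper side, rose from 14.2 ± 0.29 to 21.3 ± 0.0849 TPM. Genes often used as stable references also moved, with 3 of 6 higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 0.594). GAPC1 (AT3G04120) rose from 165 ± 5.84 to 1061 ± 86.5 TPM, UBQ10 (AT4G05320) from 831 ± 18.3 to 2063 ± 58.4 TPM, with 6.7% of its windows shared with other genes, and ACT2 (AT3G18780) fell from 754.5 ± 3.27 to 435 ± 19.5 TPM. These 3 directions held under each scaling tried.

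**Figure D2:**
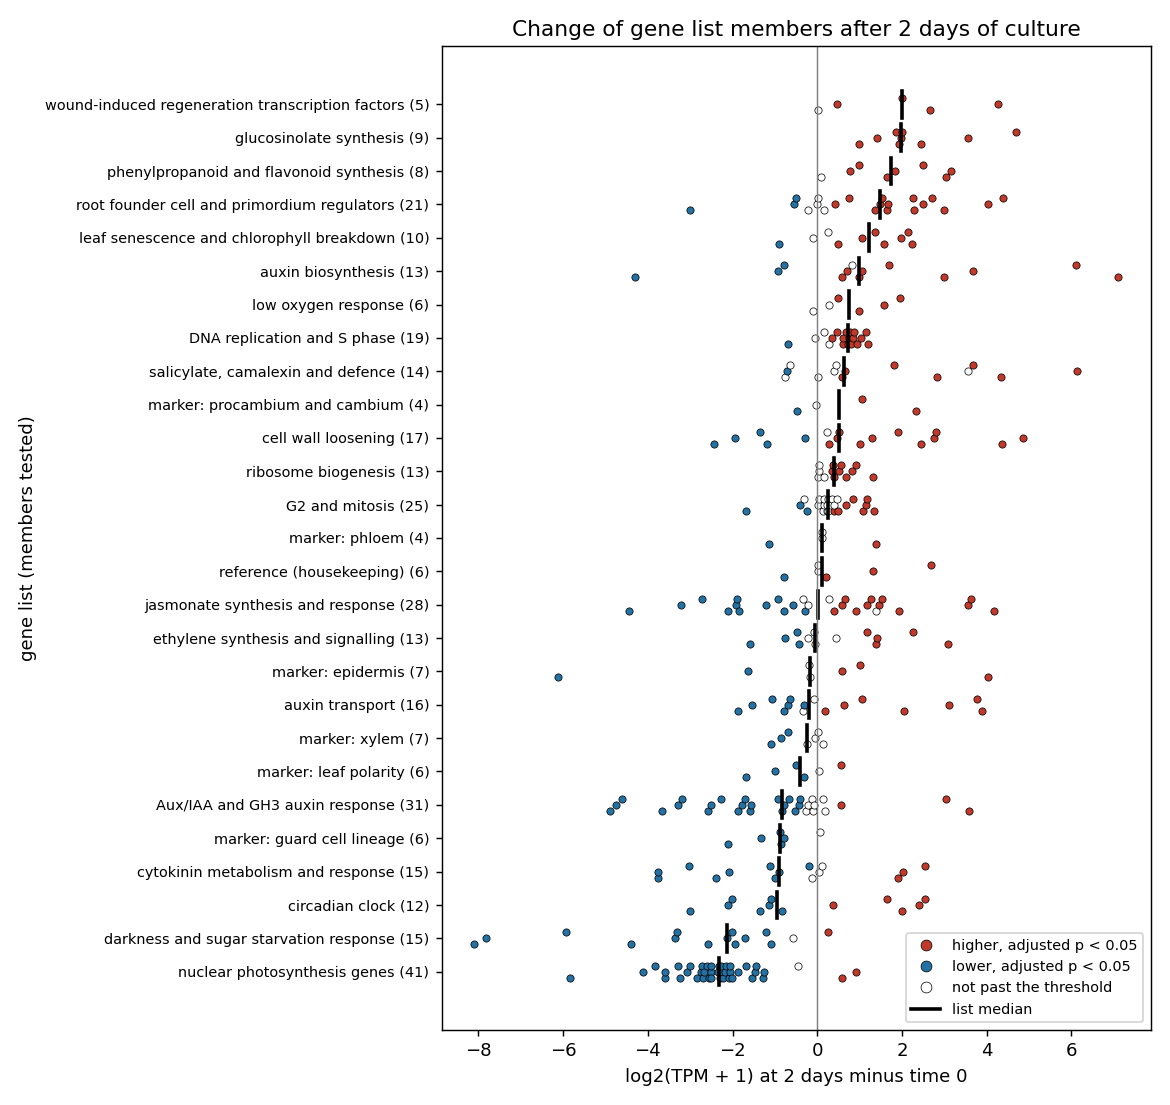
Log2(TPM + 1) at 2 days minus time 0 (horizontal axis) for every tested member of each gene list (vertical axis, with the number of members tested), ordered by list median, which a black bar marks. Filled points passed limma's test at an adjusted p below 0.05 (red higher, blue lower) and open points did not; 38 of 41 photosynthesis genes lie to the left of 0 as blue points and 9 of 9 glucosinolate genes to the right as red points.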

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

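Averaging the time 0 libraries and keeping list members without a paired symbol were the alternatives chosen after seeing the data. Of 84 named genes, 80 had the same direction and call in every alternative in which they were tested, and PIF5, CYCD3;2, TMO6 and ASA1 lost their call in some, as given with each. 0 results for named genes or lists reversed, which was counted only where the main fit or the alternative gave a call. Medians of some uncalled lists did change sign over the alternatives. That of the jasmonate list ran from -0.19 to 0.49 and that of the ethylene list from -0.17 to 0.05. Most named genes were picked for large called changes, so their stability does not describe calls in general. Of 13121 genes called in the main fit, 12013 kept call and direction after quantile normalization and 12244 with the replicate block. Fewer did so when a library was left out. Requiring at least 2-fold changes left 2958 higher and 1982 lower genes, since the added condition removes small changes, and an adjusted p below 0.01 left 6099 and 4323. With an estimated correlation 0 of 27 lists were called by camera in limma (smallest unadjusted p 0.0628, so 0 below 0.05). Otherwise 6 of the 10 called lists kept their call in every alternative, and 15 of the 17 others stayed uncalled. Leaving out 1 library gave 5773 to 7118 higher and 4021 to 5572 lower genes and 9 called lists. The replicate number as a block gave 7101 higher and 5283 lower genes and 8 called lists, with the wound-induced factors at an adjusted p of 0.0524 (0.0363 to 0.277 over the alternatives) and ribosome biogenesis at 0.0519 (0.0069 to 0.063). The correlation of deviations of same-numbered libraries was -0.0674, so the numbers are not taken to pair libraries. Time 0 libraries were closer to each other than 2-day libraries (spread of the log2 ratio 0.0862 against 0.143 for genes of 10 to 100 TPM). Without depth it cannot be tested whether they differ by more than sampling noise, and averaged into 1 sample they gave 5868 higher and 4112 lower genes. The unknown depth also leaves the error of low values, such as those of WOX5 or LBD29, without a counting bound.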

Other observations

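The gene families, the genes Prx37, PRXR1, AT4G12495, AT4G12490, GPT2, LHCB2.2 and LHCB2.3, and all tests except the rescaling test, the search for LHCB1 windows and the sugar test were chosen after the results they bear on were seen. Beyond the fixed lists, tested genes were grouped by identical product descriptions in the reference, and 162 families with at least 10 tested genes were compared with the other genes by camera. Of these, 5 passed upwards and 7 downwards, and 0 passed with an estimated correlation (adjusted p = 0.96 for each of the 12). The peroxidase superfamily stood out, with 31 of 38 genes higher and 3 lower (median log2 difference 2.82, camera adjusted p = 8.14e-06). Its members include PRX52, Prx37 (0.03 and 0 TPM at time 0, 274.14 and 154.05 TPM at 2 days) and PRXR1, which was already abundant at time 0 (1232 ± 16.1 TPM) and reached 5978 ± 350.05 TPM (SD, n = 2). Enzymes of the FAD-binding Berberine family were higher in 15 of 17 genes and lower in 1 (median 2.34, camera adjusted p = 0.00266), GDSL-like lipases in 29 of 40 with 5 lower (median 0.95, camera adjusted p = 0.00799), lipid-transfer-like proteins in 23 of 35 with 8 lower (median 1.43, camera adjusted p = 0.0388), and L7Ae-type ribosomal proteins in 10 of 11 with 0 lower (median 0.73, camera adjusted p = 0.0338).

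Among families that camera placed lower, SAUR-like auxin-responsive genes were lower in 36 of 57 and higher in 16 (median -0.98, camera adjusted p = 0.0338), and TIR-NBS-LRR disease resistance genes were lower in 24 of 41 and higher in 7 (median -0.47, camera adjusted p = 0.00928). FKBP-like isomerases were lower in 9 of 12 and higher in 3 (median -1.55, camera adjusted p = 0.0388), rhodanese-like proteins in 9 of 10 with 1 higher (median -1.06, camera adjusted p = 0.00799) and plastid fibrillins in 7 of 10 with 0 higher (median -0.75, camera adjusted p = 0.0212). Mitochondrial transcription termination factors were lower in 11 of 29 with 0 higher (median -0.27, camera adjusted p = 0.0388). A family of 167 pentatricopeptide repeat (PPR) proteins also passed (median -0.10, camera adjusted p = 0.0388), but most of its members did not pass singly (48 lower, 13 higher), and the other 2 PPR families, with 30 and 18 tested genes, did not pass (camera adjusted p = 0.159 and 0.319). The sign of the median of all 12 families was the same under TMM scaling, quantile normalization and rescaling. The highest gain of any tested gene, in AT4G12495 from 1.35 and 0.01 TPM to 7051.45 and 7019.31 TPM, is uncertain, since 100% of its windows overlap AT4G12490 on the opposite strand. The EARLI1 and AZI1 genes of the same cluster share 0% of their windows with other genes. The glucose 6-phosphate transporter gene GPT2 rose from 0.09 ± 0.0141 to 260 ± 86.6 TPM (SD, n = 2, limma adjusted p = 1.33e-05).

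The fall of nuclear photosynthesis transcripts, by a median of 2.31 on the log2 scale, was set against technical and tissue explanations. If TPM scaling by a few abundant genes were the cause, the median would approach 0 after rescaling without organelle genes and the 100 most abundant genes, but it was -2.44. With a smaller share of green cells as the only change in the tissue, markers of the other cell types would rise alike. Of 22 tested xylem, phloem, procambium and epidermis markers 7 were lower and 6 higher. They ranged from PDF1 and XCP2 (log2 differences of -6.11 and -1.10) to WOX4 and CER1 (2.32 and 4.02). Marker genes may also be regulated within their own cells, so this split cannot decide the question. A smaller share of green cells may account for part or all of the fall. A response of the leaf to darkness, detachment or medium stays open and was not tested, since the design varies these together. A possible difference in clock phase, described below, was not tested for these genes and stays open too.

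Against this fall, LHCB2.1 and LHCB2.2 were higher at 2 days, by 0.92 and 0.57 on the log2 scale, but LHCB2.2 (limma adjusted p = 0.0134) lost its call after quantile normalization (adjusted p = 0.0662) and without time 0 replicate 1 (0.0748) or replicate 2 (0.0827), within 0.00239 to 0.0827 over the scalings and libraries left out. The copies share 21.9% and 28.2% of their windows with each other and LHCB2.3 shares 0% with them, so that reads moved from LHCB2.2 to LHCB2.1 would lower LHCB2.2, which was higher in each of these settings. A share of 0 of their 50-base windows occurs in an LHCB1 transcript, which argues against reads of LHCB1 transcripts assigned to LHCB2 as the source. The direction argues against it as well. The summed TPM of LHCB1 fell (log2 differences of -2.55 to -2.19), so a constant share of its reads would have lowered LHCB2. LHCB2.3, of whose windows 38.6% overlap a gene on the opposite strand, did not pass (log2 difference -0.45). What raised LHCB2.1 stays open.

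Genes of darkness and sugar starvation fell although the explants were kept in the dark, and a candidate explanation is that the tissue held more sugar at 2 days, on medium with sucrose, than at time 0. In sugar-responsive genes outside the list, fixed before their values were examined, the 2 induced genes rose (APL3 from 4.72 ± 0.00707 to 273 ± 38.6 TPM, BAM5 from 0.62 ± 0.0141 to 9.68 ± 2.44 TPM). All 5 of 5 repressed genes fell (STP1, bZIP1, AKINBETA1, BGAL4 and KMD4, with log2 differences of -3.89, -3.53, -3.25, -1.27 and -0.74), a difference of medians of 7.38. Genes repressed by sugar are higher in sugar starvation, so their fall largely restates the fall of the list. Only the rise of the 2 induced genes adds to it, and that rise goes with the explanation. A difference in clock phase between the groups may also contribute, since transcripts of some such genes follow the time of day. Of clock-controlled genes outside the clock list, 4 of 6 morning genes rose and 1 fell (median 0.83). Of the evening genes 3 of 4 fell (median -1.12) while GRP8 rose by 1.84. The difference of medians of 1.96 goes with such a phase difference. Because the clock controls these genes and the clock list had already been seen to change, it largely restates that change. It cannot tell a phase difference from another change of the clock. The tests do not separate the sugar and clock explanations, and detachment itself stays open.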
